A study of Mus musculus with 16 samples.

How the data were processed

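The study measured single-strand breaks by SSB-seq in mouse embryonic stem cells of strain C57BL/6JRj, grown in serum-free 2i medium with LIF. Per the labels' protocols, genomic DNA was nick-translated briefly with E. coli DNA polymerase I in the presence of digoxigenin-dUTP and chain-terminating ddNTPs, fragmented by sonication and restriction digestion, and pulled down with an anti-digoxigenin antibody; pulled-down and input DNA were made into libraries. The 16 libraries fall into 8 groups by genotype (wild type or Tdg knockout), treatment (DMSO, or 5 nM talazoparib for 24 h) and kind (IP with 3 libraries, input with 1). How long cells stayed in DMSO is not given in the sources used here. The labels' descriptions name 2 flow cells per genotype, not shared between genotypes.

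The submitters' processing notes name Bowtie2 2.3.4.2, Picard 2.9.2, HOMER 4.11, R 3.6 and the genome build mm10, without roles or settings. The 4 deposited tables, 1 per condition, have the column names of HOMER's findPeaks per the file headers, and each table holds 1 value per peak for all IP libraries of its condition, so the authors pooled the replicates. How they filtered, merged or paired IP with input libraries is not given in the sources used here. Coordinates are printed as the tables give them, and whether starts count from 0 or 1 is not stated.

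Per the file headers, the authors' normalized tag count is the IP signal in a peak, and its values bear out tags per 10000000 IP tags, used here as the signal unit. The deposited input column holds tags of the input library in the peak, a signal that comes in steps of 0.5 tags. A further column, of another unit (other), holds the authors' IP tags scaled to the input library's total. The authors' fold is the ratio of scaled IP tags to input tags: recomputed from those columns it matched the deposited ratio within 1% for 100% of peaks, and its lowest value was 4.00 in every list. The deposited p-value of each peak equalled a Poisson probability of the scaled IP tags given the input tags, within 0.05 on a log10 scale, for 94.9% to 96.7% of peaks, with a maximum of 8.32e-05. The authors' score is HOMER's peak score, which was used only to rank peaks within a list, and the deposited clonal fold, also a score, entered no result. These values describe peaks within 1 list. A fold or score in one list set against another list's shows no change.

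Input totals were taken from the factor between the normalized and the scaled tag columns. IP totals were not given directly. They were estimated from the low normalized tag counts, under 6, which are whole multiples of a step fixed by the total, and 99.98% to 100% of those values fell on the step within 0.0051. The totals ran from 66.4 to 87.0 M IP tags and from 24.5 to 38.1 M input tags. Tag density at a peak, IP or input, is tags per bp divided by the library's mean over the 2648 Mb of sequenced bases of chromosomes 1 to 19, X and Y. All density and overlap results use these chromosomes, and peaks on the mitochondrial genome and unplaced contigs, 14 to 37 per list, are treated separately.

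The planned tests on read counts per library, for replicate agreement and for a talazoparib effect at shared peaks, could not be run because the tables hold no values per library. Comparisons therefore rest on peak positions, and their p-values compare lists, not conditions. Intervals cover counting or positional error only, and leave out differences between cultures, libraries and flow cells. No per-library value was given, so replicate libraries could not be compared with each other.

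Overlap of 2 lists was the share of peaks with at least 1 bp in a peak of the other list, with a Wilson 95% interval, tested one-sided against 1000 circular shifts of a list along each chromosome by at least 100 kb. Regions of all lists were merged where they overlapped, and each region was counted under 1 of 15 combinations of lists. A region found in 1 list only entered later steps as a peak set of its own, which gave 8 peak sets. Peak centres were annotated with GENCODE M21 on GRCm38.p6, the assembly behind mm10, whose chromosome names and lengths matched, in the order promoter (1 kb upstream to 100 bp downstream of a start), transcription end (100 bp upstream to 1 kb downstream), exon, 5' UTR, 3' UTR, intron and intergenic. Shares have 95% intervals from 1000 resamples of 10 Mb blocks, and were set beside 100 shifted copies. Differences in share were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 49 tests (7 features and 7 pairs of sets). Peaks are not independent of their neighbours, so the block intervals are the more cautious measure. The talazoparib effect was compared between genotypes as a ratio of odds ratios with block resampling.

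Gene lists were tested as the number of genes with a peak in the gene body or within 5 kb, against 10000 random lists of the same size drawn from 32049 genes in the same 10 length classes, two-sided, with adjustment over 120 tests. The 15 lists are naive pluripotency, primed epiblast, developmental regulators under polycomb, genes with promoters linked to TDG, germline genes with methylated promoters, imprinted genes, DNA methylation and demethylation, base excision and strand break repair, large late-replicating genes, highly transcribed housekeeping genes, 2-cell-like genes, extraembryonic endoderm markers, fibroblast markers, histone genes and chemosensory receptors. All listed members were found in the annotation, Adprs under its older symbol Adprhl2. Some genes are on more than 1 list (Dnmt3b, Sfrp2, Hoxa10, Hoxd13, Foxa2, Gata4, Gata6, Sox17 and Pdgfra). Base composition (GC percent, CpG per 100 bp, soft-masked percent) of peaks was compared with 1000 shifted copies, two-sided. Peaks called CpG-rich had at least 50% GC and an observed over expected CpG ratio of at least 0.6.

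Named regions are the 5 peaks with the highest score in each list and in each set found in 1 list only, at most 1 per 100 kb. Named genes are the 5 protein-coding genes with most peaks in the body per list, Tdg, and up to 4 members of each gene list with most peaks over the 4 lists, with ties in order of symbol. Results for a few of these named genes and regions are not reported here. The gene lists, the naming rule, the tests and the first set of alternatives were chosen before the data were examined. Alternatives were a stricter fold (1.5 times the lowest, that is 6.0), autosomes only, peaks within 1 kb merged, a reciprocal overlap or peaks extended by 1 kb, lists of equal length by score, randomly placed peaks, promoters within 1 or 5 kb of a start, a window around the start only, matching on CpG density in 5 classes per length class, and 500 bp around the peak centre. Chosen after seeing the data were a minimum of 3 input tags, an IP density of at least 2 or 4 times the genome mean, equal list lengths by normalized tag count, and gene lists reduced to the first gene of each cluster of members whose 5 kb windows overlap. Input totals differed between lists, so 3 input tags stand for a higher input density where the input was smaller.

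The procedures were tested on simulated data. For the overlap test, 40 pairs of unrelated lists of 3000 peaks gave 0 with p under 0.05, and 40 pairs with 5.0% planted sharing were all called, with 5.00% recovered. The simulated peaks were placed evenly at random along the chromosomes, while the deposited peaks gather at promoters and in GC-rich DNA. How the test behaves for unrelated lists that share such a preference was therefore not simulated. For the gene list test over 32049 genes, 9 of 400 lists of 30 long genes without a planted excess and 332 of 400 with one had p under 0.05. Block intervals held the true share in 278 of 300 simulated lists, so they are slightly too narrow. The totals worked out from steps were off by at most 0.0121% in 10 simulated lists. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.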

Results

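Single-strand break sequencing (SSB-seq) marks nicks in genomic DNA by letting E. coli DNA polymerase I add digoxigenin-labelled nucleotides at free 3' ends, after which labelled fragments are pulled down with an antibody and sequenced. It was applied to mouse embryonic stem cells grown in 2i medium with LIF, which holds them in a naive state. The cells either expressed the thymine DNA glycosylase TDG, which excises thymine from G:T mismatches and oxidised forms of 5-methylcytosine during DNA demethylation, or had lost it through 4-OHT-induced excision of a Tdg minigene. The labels call the first wild type (WT here) and the other is called KO here. Each was treated with DMSO or with 5 nM talazoparib, an inhibitor of poly(ADP-ribose) polymerases, for 24 h. The comparisons ask where single-strand breaks are found in these cells, and how the inhibitor and the loss of TDG change that. There were 16 libraries: 3 immunoprecipitated (IP) libraries and 1 input library in each of the 4 conditions. For each condition 1 peak list was used, called on the IP libraries together, so no value below has a spread between replicates, and every p-value compares lists rather than conditions. WT and KO libraries were sequenced on different pairs of flow cells, so genotype and sequencing batch cannot be told apart.

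The lists were built on input libraries of 38.1 M tags (WT DMSO), 24.5 M (WT talazoparib), 24.8 M (KO DMSO) and 28.3 M (KO talazoparib). The pooled IP totals, worked out from the steps of the normalised tag counts, were 87.0, 83.8, 69.2 and 66.4 M tags in the same order. Peaks numbered 28559 in WT DMSO, 15544 in WT talazoparib, 35459 in KO DMSO and 23983 in KO talazoparib, and covered 21.9, 11.5, 31.9 and 19.5 Mb. Median peak length ran from 629 to 722 bp. At the peaks the IP was only modestly enriched: the median tag density was 2.00, 2.11, 2.53 and 2.91 times the genome mean of the same pooled IP. Input density at the same peaks was low, with medians of 0.417, 0.306, 0.426 and 0.561 times the input's own genome mean, and 81.1% to 96.9% of peaks lay where the input was below its mean. Every listed peak had a fold of at least 4 over input, so peaks of modest IP density could be listed only where input was low. The authors' fold over input therefore rested on few input tags. The median peak had 3.5, 2, 3 and 4 of them, and 60.7% of WT talazoparib peaks had fewer than 3.

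**Figure D1:**
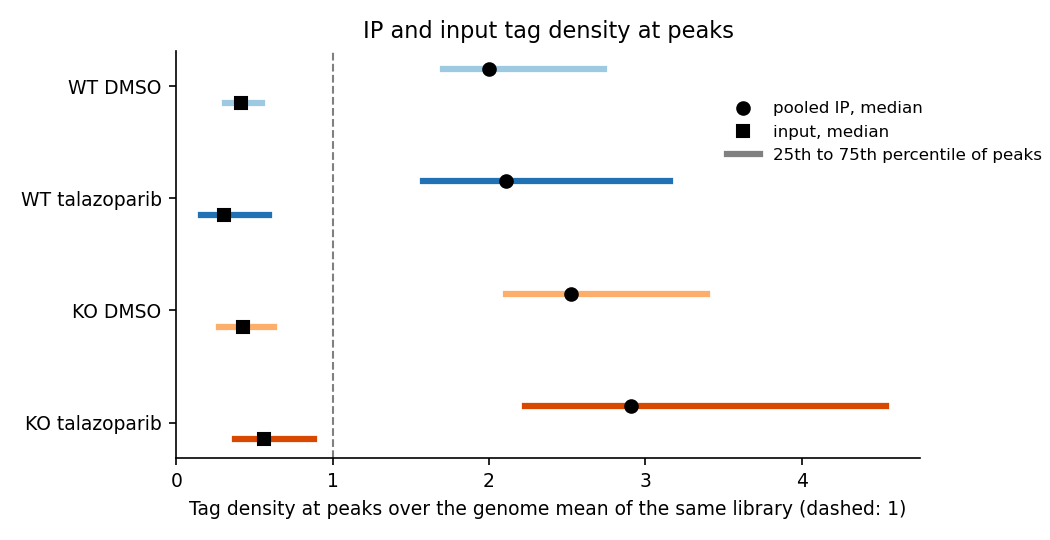
Tag density at the peaks of each list, as a multiple of the genome mean of the same library; circles are medians of the pooled IP, squares are medians of the input, and bars run from the 25th to the 75th percentile of peaks. IP medians lie between 2.00 and 2.91 and input medians between 0.306 and 0.561, below the dashed line at 1.

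Peaks were gathered at gene starts and in GC-rich DNA in all 4 conditions. Promoters, taken as 1 kb upstream to 100 bp downstream of a transcription start, held 25.6% of WT DMSO peaks (95% block interval 24.6 to 26.6), 34.1% of WT talazoparib peaks (32.9 to 35.3), 24.5% of KO DMSO peaks (23.5 to 25.4) and 30.3% of KO talazoparib peaks (29.3 to 31.4). Peaks shifted along their chromosomes fell in promoters in 2.65% to 2.70% of cases, so the excess was 9.06-fold to 12.8-fold. The 5' UTR held few peaks, 2.04% to 2.89%, but stood 19.4-fold to 28.9-fold above shifted positions. Other exons were at 2.74-fold to 2.93-fold. Introns were below shifted positions at 0.748-fold to 0.873-fold, and intergenic DNA at 0.442-fold to 0.521-fold. Median GC content of the peaks was 52.6%, 54.8%, 52.4% and 53.5% for WT DMSO, WT talazoparib, KO DMSO and KO talazoparib, against 41.9% after shifting. CpG dinucleotides numbered 2.00, 3.18, 2.10 and 2.40 per 100 bp against 0.644 to 0.659. Soft-masked repeat sequence made up a median of 9.82% to 10.8% of a peak against 24.2% to 24.5%. Each of these 12 differences in composition had a two-sided permutation p of 0.002, the smallest that 1000 shifts can give.

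**Figure D2:**
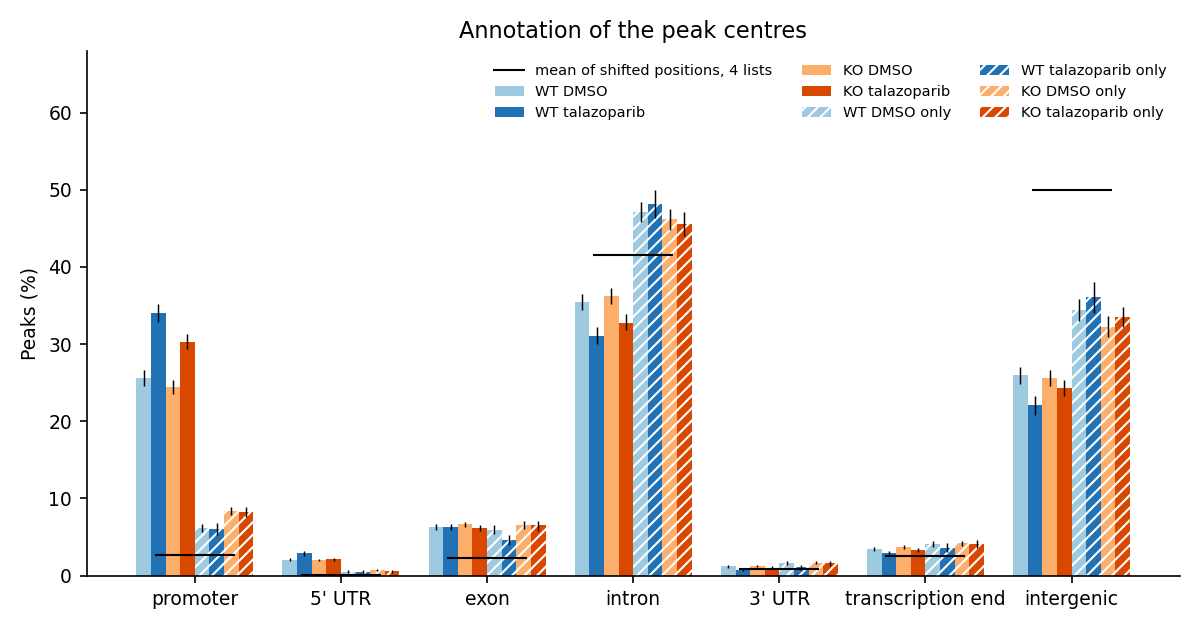
Share of peaks whose centre lies in each annotated feature; solid bars are the 4 full lists, hatched bars the regions found in 1 list only, error bars are 95% intervals from resampling 10 Mb blocks, and black lines are the mean of shifted positions. Promoters hold 24.5% to 34.1% of the full lists and 6.00% to 8.41% of the regions found in 1 list only.

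Among fixed gene lists, histone genes, housekeeping genes, naive pluripotency genes and base excision or strand break repair genes carried peaks more often than random genes of the same length in all 4 conditions. That held with all peaks counted, and each of these lists lost its call in some conditions at a fold of at least 6. Histone genes, which supply nucleosomes in S phase, led with matching on length alone and all members counted. Of the 68, 59, 46, 61 and 63 had a peak in WT DMSO, WT talazoparib, KO DMSO and KO talazoparib, 2.59, 2.81, 2.33 and 2.9 times the expected number. Peaks stood at the chromosome 13 genes Hist1h1d (3 in every list) and Hist1h3d (3, 1, 3 and 3), with Hist1h2be at 4, 1, 2 and 2 and Hist1h3c at 3, 1, 3 and 2. Housekeeping genes had 24, 22, 25 and 23 of 25 members with a peak, at 2.05, 2.56, 1.93 and 2.09 times expectation. Examples are the glycolytic enzymes Eno1 (3, 2, 6 and 5 peaks) and Pkm (4, 3, 6 and 2), the cytoskeletal Actb (5, 2, 3 and 3) and the ribosomal Rpl3 (4, 1, 4 and 4). Each of these 8 tests had an adjusted permutation p of 9.23e-04, the smallest that 10000 random lists gave after adjustment over 120 tests of 15 lists in 8 peak sets. Histone genes lie in tight clusters, so 1 peak can count for several of them, while the random lists hold scattered genes. With 1 gene kept per cluster, an alternative chosen after seeing the data, 13, 10, 15 and 15 of 17 had a peak, at 2.31, 2.48, 2.3 and 2.80 times expectation (adjusted permutation p = 0.00400, 0.0114, 9.23e-04 and 9.23e-04). Housekeeping genes were then above histone genes in WT talazoparib, at 2.54 times expectation.

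Naive pluripotency genes, the transcription network that 2i medium sustains, had a peak at 24 of 26 members in WT DMSO, 20 in WT talazoparib, 25 in KO DMSO and 22 in KO talazoparib, 1.84, 2.00, 1.72 and 1.77 times expectation (adjusted permutation p = 9.23e-04 in each). The orphan nuclear receptor gene Esrrb (chromosome 12, 86361117 to 86521628) held the most, with 11, 6, 16 and 15 peaks. Tfcp2l1, a transcription factor of the same network, had 3, 1, 9 and 5, the ES cell marker Fbxo15 had 4, 2, 5 and 4, and Klf2 had 2, 3, 5 and 3. At a fold of at least 6 naive pluripotency genes did not pass in WT DMSO (1.27 times) or KO talazoparib (1.79 times). In WT talazoparib they did not pass with the window around the start only (1.63 times) or with at least 3 input tags (1.78). Nor did they pass there at an IP density of at least 2 times the mean (1.59 times). At 4 times the mean they passed in no list (1.92, 1.42, 1.75 and 1.87 times). Repair genes had 26, 22, 29 and 26 of 29 members with a peak, at 1.59, 1.71, 1.62 and 1.67 times expectation, with adjusted permutation p = 0.00248, 0.00733, 9.23e-04 and 9.23e-04. The uracil glycosylase gene Ung carried 4, 2, 5 and 2 peaks, Aplf 3, 4, 2 and 3, Parp3 4, 1, 3 and 2, and the AP endonuclease gene Apex1 2 in every list.

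DNA methylation and demethylation genes stood above expectation in WT DMSO (23 of 25, 1.60 times, adjusted permutation p = 0.00525), KO DMSO (23, 1.45 times, p = 0.00733) and KO talazoparib (21, 1.52 times, p = 0.00778). In WT talazoparib they numbered 17, at 1.49 times and an adjusted permutation p of 0.0835. Tet1, which oxidises 5-methylcytosine, had 6, 2, 10 and 6 peaks, Trim28 5, 4, 4 and 7, the de novo methyltransferase gene Dnmt3a 5, 0, 7 and 4, and Tet2 4, 2, 5 and 2. With the window around the start only, DNA methylation genes did not pass in WT DMSO, KO DMSO or KO talazoparib (1.40, 1.42 and 1.39 times, adjusted permutation p = 0.238, 0.107 and 0.321). At a fold of at least 6 they did not pass in KO DMSO (1.41 times, adjusted permutation p = 0.222) or KO talazoparib (1.97 times, p = 0.0690). Primed epiblast genes passed in WT DMSO (14 of 16, 1.67 times, adjusted permutation p = 0.0158), KO DMSO (15, 1.62 times, p = 0.0102) and KO talazoparib (14, 1.76 times, p = 0.00985), and not in WT talazoparib (9, 1.39 times, p = 0.472). None of the 3 passed with peaks on autosomes only (1.58, 1.43 and 1.54 times, adjusted permutation p = 0.0667, 0.148 and 0.129) or at a fold of at least 6 (1.94, 1.18 and 1.2 times, p = 0.250, 0.916 and 1.00). Their members with most peaks were Etv5 (6, 3, 10 and 6), the Wnt effector gene Lef1 (5, 0, 5 and 3), Foxd3 (2, 2, 3 and 3) and Dnmt3b (2 in every list). Developmental regulators under polycomb control, silent in ES cells, passed in WT DMSO (34 of 50, 1.41 times, adjusted permutation p = 0.0206), KO DMSO (42, 1.56 times, p = 9.23e-04) and KO talazoparib (34, 1.48 times, p = 0.00733), and not in WT talazoparib (24, 1.3 times, p = 0.248). Examples are the homeobox genes Lmx1b (7, 3, 6 and 3) and Pax7 (3, 1, 4 and 2), Tfap2a (3, 2, 5 and 2) and Six2 (3, 1, 4 and 2). At a fold of at least 6 developmental regulators no longer passed in WT DMSO, KO DMSO or KO talazoparib (1.09, 1.45 and 0.657 times). With the window around the start only, the call was lost in WT DMSO (1.08 times, adjusted permutation p = 0.948) and KO talazoparib (1.15 times, p = 0.759). Imprinted genes passed in WT DMSO (31 of 39, 1.44 times, adjusted permutation p = 0.00985) and KO DMSO (31, 1.3 times, p = 0.0360), and not in KO talazoparib (28, 1.36 times, p = 0.0531) or WT talazoparib (18, 1.05 times, p = 1.00). These also lie in clusters, and with 1 gene kept per cluster neither DMSO list passed (1.36 and 1.23 times, adjusted permutation p = 0.0856 and 0.248). KO talazoparib did pass with peaks on autosomes only (1.39 times, adjusted permutation p = 0.0417), with equal numbers of best-scoring peaks (1.5 times, p = 0.0199) and at an IP density of at least 2 times the mean (1.42 times, p = 0.0285). Kcnq1 had 7, 2, 9 and 5 peaks, H13 4, 2, 8 and 7, Gnas 6, 1, 6 and 4, and Usp29 2, 3, 7 and 4. Whether any list differed between conditions was not tested.

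Chemosensory receptor genes, which lie in large silent arrays, were nearly free of peaks: 36, 22, 41 and 36 of 1464 had one, 0.0540, 0.0445, 0.0553 and 0.0573 times expectation (adjusted permutation p = 9.23e-04 in each). The few with most peaks were Olfr90 (2 in every list), Olfr1416 (2, 1, 1 and 1), Olfr718-ps1 (2, 0, 1 and 2) and Olfr94 (0, 0, 3 and 2). None of 16 genes of the 2-cell-like state, such as the Zscan4 cluster, had a peak in any list (adjusted permutation p = 0.00480, 0.0251, 9.23e-04 and 0.00582). Both families consist of similar copies, to which short reads are hard to assign. Germline genes with methylated promoters showed no excess or deficit past the threshold (9, 7, 16 and 11 of 23; 0.652, 0.630, 1.05 and 0.827 times), with peaks at Tdrd1 (1, 1, 2 and 2), Brdt (1, 0, 2 and 2), Hormad1 (2, 1, 1 and 1) and Smc1b (1 in every list). The same held for 26 large, late-replicating genes (21, 16, 21 and 21; 1.14, 1.06, 1.07 and 1.19 times), among them Auts2 (5, 6, 8 and 9), Cdh13 (6, 4, 9 and 7) and Magi2 (3, 5, 4 and 2). Of 5 genes whose promoters have been linked to TDG, 2, 1, 3 and 2 had a peak, too few to pass any test: Sfrp2 had 1, 0, 2 and 0 peaks, Twist2 1, 1, 1 and 0, Hoxd13 0, 0, 1 and 1, and Rarb 0, 0, 0 and 2. Markers of other cell types did not pass the threshold with matching on length and all peaks. At an IP density of at least 2 times the mean, fibroblast genes showed a deficit in WT DMSO (0.296 times, adjusted permutation p = 0.0485). Extraembryonic endoderm genes had 11, 6, 9 and 13 of 16 members with a peak (1.12, 0.757, 0.842 and 1.38 times), led by Sparc (10, 2, 7 and 3), Lama1 (4, 3, 2 and 3), Hnf4a (3, 0, 6 and 2) and Col4a2 (3, 1, 4 and 1). Fibroblast genes had 6, 4, 7 and 6 of 15 (0.704, 0.6, 0.754 and 0.736 times), led by Fn1 (4, 3, 4 and 2), Col1a1 (3, 1, 4 and 1), Pdgfra (2, 1, 0 and 4) and Loxl1 (1, 0, 2 and 2).

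**Figure D3:**
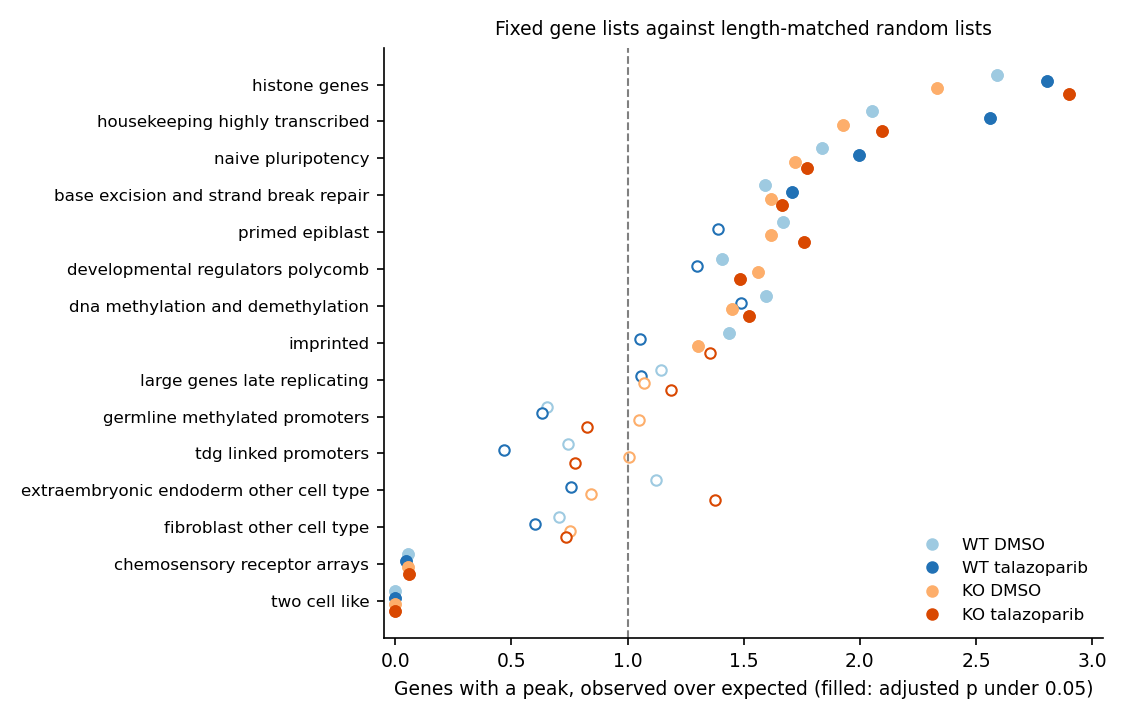
Number of genes with a peak in the gene body or within 5 kb, divided by the mean of random lists matched on gene length, for the 15 fixed lists (vertical axis) and the 4 peak lists (colours); filled points have an adjusted permutation p under 0.05. Histone genes lie at 2.33 to 2.9 and chemosensory receptor genes at 0.0445 to 0.0573.

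The gene list excesses became smaller when base composition was taken into account. With random genes matched on CpG density as well as length, the number of lists above expectation went from 8, 4, 8 and 7 to 2, 1, 1 and 2. Histone genes went to 1.25, 1.28, 1.15 and 1.37 times expectation and stayed past the threshold in WT DMSO and KO talazoparib. All members of each histone cluster were counted here, so 1 peak can again count for several genes. Keeping 1 gene per cluster was not combined with this matching. Housekeeping genes went to 1.27, 1.51, 1.22 and 1.28 times and passed in WT talazoparib. Repair genes went to 1.18, 1.24, 1.21 and 1.23 times and passed in KO DMSO. Naive pluripotency genes went to 1.31, 1.41, 1.24 and 1.27 times and passed in none. Nor did primed epiblast genes (1.02, 0.806, 1.03 and 1.06 times), DNA methylation genes (1.19, 1.1, 1.1 and 1.14) or imprinted genes (1.11, 0.815, 1.02 and 1.05). Large, late-replicating genes rose to 1.71, 1.66, 1.46 and 1.73 times and passed in WT DMSO and KO talazoparib, where they had not before. Developmental regulators moved below expectation, at 0.803, 0.7, 0.922 and 0.832 times, a deficit that passed in WT DMSO and WT talazoparib (adjusted permutation p = 0.0203 and 0.0223). Chemosensory receptor genes were still low, but at 0.381, 0.358, 0.353 and 0.402 times. For the 2-cell-like genes only 0.380 to 0.806 genes with a peak were expected, and their deficit passed in no list (adjusted permutation p = 1.00 in each). Extraembryonic endoderm genes fell below expectation in KO DMSO (9 of 16, 0.664 times, adjusted permutation p = 0.0416).

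The protein-coding genes with most peaks in their bodies were long. Gm20388, an annotated locus of 4435 kb on chromosome 8 (119910841 to 124345722) that spans other genes, had 188, 92, 227 and 150 peaks in WT DMSO, WT talazoparib, KO DMSO and KO talazoparib. Gse1, which lies inside it, had 26, 13, 41 and 23. The growth factor receptor gene Fgfr2, annotated over 2961 kb on chromosome 7 (130162451 to 133123350), had 53, 30, 77 and 44. Ryr1, which encodes the calcium release channel of skeletal muscle, had 20, 4, 11 and 10. Rnf220 had 15, 10, 20 and 11, the zinc transporter gene Slc39a11 had 15, 9, 23 and 19, and Camta1 had 18, 9, 23 and 14. The overlapping loci Gm42416 and Gm37013 on chromosome 18, which run across the clustered protocadherins, had 17, 8, 27 and 15 and 17, 8, 25 and 14.

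The Tdg gene itself (chromosome 10, 82629828 to 82650799, plus strand) had a peak at its start with DMSO in both genotypes and none in either talazoparib list. In WT DMSO the peak lay at 82629628 to 82630254, in the promoter, with 20.9 normalised tags (tags per 10000000 IP tags), a fold of 5.68 over input and an IP density of 8.84 times the genome mean. In KO DMSO it lay at 82629765 to 82630622, centred in an intron of the annotation, with 8.60 normalised tags, a fold of 6.11 and 2.66 times the mean. KO DMSO had a further peak just past the gene, at 82652540 to 82653171. The promoter of the neighbouring 1190007I07Rik carried a peak in every list, with 20.9, 16.9, 27.0 and 29.1 normalised tags. The labels place the deletion in a Tdg minigene, and a peak list shows where tags gather and not whether a gene is present, so these values do not check the genotype labels.

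Talazoparib in the presence of TDG was compared through the 2 WT lists. The list with the inhibitor was 0.544 times as long as the DMSO list. The peaks that were found in both held more tags. Of 28539 DMSO peaks, 8103, 28.4% (Wilson 95% interval 27.9 to 28.9), shared at least 1 bp with a talazoparib peak. Their median signal was 11.1 normalised tags against 3.97 in the others. These tags were not divided by peak length, and by fold over input the medians were close, 5.29 and 5.08. In the other direction 52.4% of the 15526 talazoparib peaks (51.6 to 53.1) overlapped a DMSO peak. The shared talazoparib peaks had more tags than the others (8.23 against 3.46) but a lower median fold (6.07 against 8.33). Both overlaps were far above circularly shifted lists, by 27.7-fold and 27.5-fold (one-sided permutation p = 0.001, the smallest these shifts can give). Shifting also moves peaks out of promoters and GC-rich DNA. A preference for such DNA in both lists would therefore give an excess too, here and in the overlaps below. Of the 26 naive network genes, 4 had a peak with DMSO and none with talazoparib, and 0 had the reverse. These 4 were Sox2, Sall4, Prdm14 and Dppa4, named after their values were seen. Among imprinted genes the counts were 13 and 0, among developmental regulators 14 and 4, among histone genes 15 and 2, among repair genes 6 and 2, and among DNA methylation genes 6 and 0. Fewer peaks overall make such losses more frequent, and no test against that was run.

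The shorter WT list was not shorter at every threshold. Among peaks with an IP density of at least 4 times the genome mean, 2340 were listed with talazoparib and 2578 with DMSO, a ratio of 0.908 (0.858 to 0.960), and at 6 times the mean 650 and 411. At a fold over input of at least 6, 10014 peaks were listed with talazoparib and 8257 with DMSO. These folds rest on unlike inputs: 22.4% of WT talazoparib peaks had only 0.5 input tags, against 1.29% of WT DMSO peaks. With at least 3 input tags the talazoparib list was the shorter one, 6119 against 19730. The share of DMSO peaks found with talazoparib moved with the threshold too, to 56.6% at an IP density of 4 times the mean and 16.6% at a fold of 6, while it stayed at least 9.92-fold above shifted lists under every alternative tried. Promoters made up more of the talazoparib list, by 8.48 percentage points (7.83 to 9.13; Fisher's exact test, adjusted p = 3.34e-76). The 5' UTR share rose by 0.815 points (Fisher's exact test, adjusted p = 8.02e-07), while introns fell by 4.33 points (6.47e-19), intergenic DNA fell by 3.88 points (1.33e-18) and 3' UTRs fell by 0.479 points (5.04e-06). The promoter difference depended on the setting. It changed sign with both lists reduced to equal numbers of best-scoring peaks (-3.63 points) or of peaks ranked by normalised tags (-5.92), at a fold of at least 6 (-2.41), and at an IP density of at least 4 times the mean (-2.02). It grew at an IP density of at least 2 times the mean (10.1), with promoters within 1 kb of a start (12.1) and with at least 3 input tags (26.2). The last setting is unlike between the lists, because the input totals were 24.5 M tags with talazoparib and 38.1 M with DMSO. There 3 tags are a higher input density with talazoparib. The peaks left had a median GC content of 61.4% with talazoparib and 54.2% with DMSO.

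**Figure D4:**
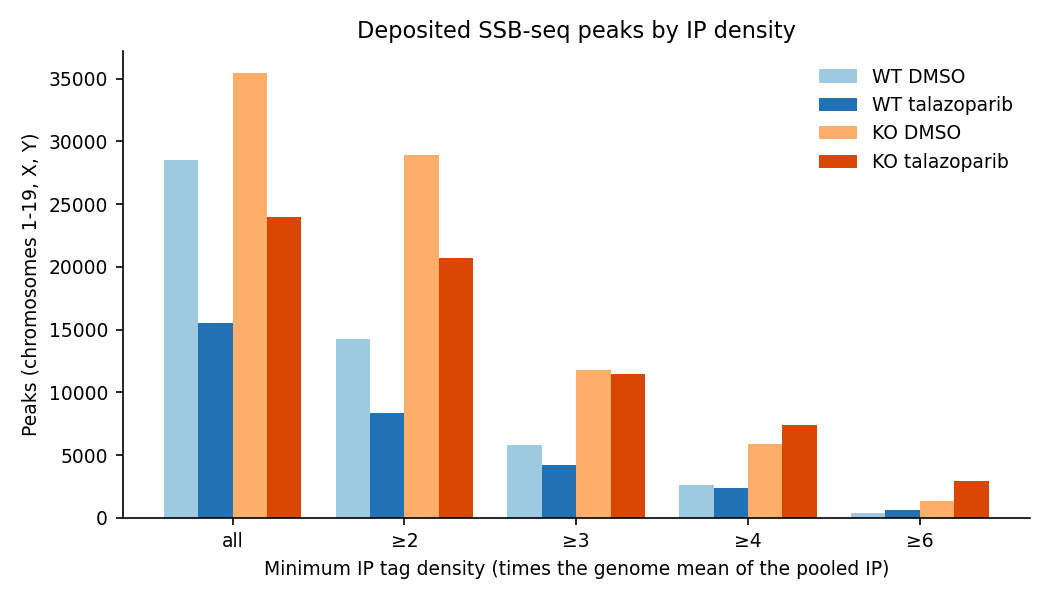
Number of peaks on chromosomes 1 to 19, X and Y in each list, in total and at rising minimum IP tag density as a multiple of the genome mean. In all peaks talazoparib lists are shorter (15526 against 28539 in WT, 23946 against 35445 in KO), and from 4 times the mean the KO talazoparib list is longer than KO DMSO (7414 against 5880).

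Without TDG, talazoparib again gave a shorter list, 0.676 times as long as with DMSO. Of 35445 KO DMSO peaks, 39.4% (38.9 to 39.9) overlapped a KO talazoparib peak, 22.2-fold above shifted lists, and 59.0% of 23946 talazoparib peaks (58.4 to 59.6) overlapped a DMSO peak, 22.5-fold above (one-sided permutation p = 0.001 for each). Shared DMSO peaks had a median of 14.2 normalised tags and the others 5.13, while their median folds over input were 6.15 and 6.47. Here 4 naive network genes had a peak with DMSO only and 1 with talazoparib only. The counts were 12 and 4 among developmental regulators, 5 and 2 among imprinted genes, 3 and 0 among repair genes, and 2 and 4 among histone genes. Extraembryonic endoderm markers went the other way, with 1 gene holding a peak with DMSO only (Gata6) and 5 with talazoparib only (Cubn, Dab2, Foxa2, Pdgfra and Sox17), named after their values were seen. No difference between these counts was tested.

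At an IP density of at least 4 times the genome mean, KO peaks were more numerous with talazoparib (7414) than with DMSO (5880), a ratio of 1.26 (1.22 to 1.31), and at 6 times the mean there were 2966 and 1373. The share of KO DMSO peaks found with talazoparib ranged from 12.9% at a fold of 6 to 77.3% at that IP density. Promoters took 5.82 points more of the talazoparib list (5.27 to 6.38; Fisher's exact test, adjusted p = 9.97e-54), and introns fell by 3.49 points (1.89e-17). Intergenic DNA fell by 1.33 points (9.71e-04). The 3' UTR and 5' UTR shares did not pass (Fisher's exact test, adjusted p = 0.0528 and 0.713). With equal numbers of best-scoring peaks the promoter difference was 2.01 points, ranked by normalised tags it was -0.966, with at least 3 input tags 2.18, and at an IP density of 4 times the mean -0.520. It stayed near its size at a fold of at least 6 (5.79) and at an IP density of at least 2 times the mean (5.41).

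Loss of TDG was compared within DMSO. The KO list was the longer one, 35459 peaks against 28559. Of WT DMSO peaks, 52.1% (51.5 to 52.7) overlapped a KO DMSO peak and 41.4% of KO DMSO peaks (40.9 to 41.9) overlapped a WT one, 20.0-fold and 19.8-fold above shifted lists (one-sided permutation p = 0.001 for each). Most strong WT peaks were found again, 89.5% of those with an IP density of at least 4 times the mean. In the other direction 39.0% of the 5880 KO peaks at that density overlapped 1 of the 2578 WT ones. Peak counts per gene were often higher in this longer KO list, though they were not tested one by one or against its length. At Esrrb the KO DMSO list had 16 peaks and the WT list 11, at Tet1 10 and 6, at Tfcp2l1 9 and 3, at Etv5 10 and 6, and at H13 8 and 4. At Tet1 and Tfcp2l1 no WT DMSO peak reached an IP density of 2 times the mean. Sparc, a matrix glycoprotein gene, went the other way with 7 and 10. So did other named genes, among them Ryr1 (11 and 20 in the body), Actb (3 and 5), Lama1 (2 and 4), Hist1h2be (2 and 4), Trim28 (4 and 5) and Lmx1b (6 and 7). Promoter share was lower in KO by a difference of -1.10 points (-1.57 to -0.653; Fisher's exact test, adjusted p = 0.00382). That difference depended on the setting. With promoters defined as 1 kb on both sides of a start it was -0.388 (Fisher's exact test, adjusted p = 0.474), with equal numbers of best-scoring peaks 0.837 (adjusted p = 0.196), by normalised tags 3.38, and with at least 3 input tags 4.29. It was larger and still negative at an IP density of at least 2 times the mean (-14.0), at 4 times (-8.11) and at a fold of at least 6 (-2.58).

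With talazoparib, 50.3% of WT peaks (49.6 to 51.1) overlapped a KO peak and 32.5% of KO peaks (31.9 to 33.1) a WT peak, each 31.2-fold above shifted lists (one-sided permutation p = 0.001). Shared KO peaks had a median of 18.1 normalised tags against 5.65 in the others. Lef1, Dnmt3a and Hnf4a had no peak in WT and 3, 4 and 2 in KO, and Esrrb had 6 and 15. The KO list was the longer one, 23983 peaks against 15544, and no gene was tested against that. Other named genes had more peaks in WT than in KO, among them Magi2 (5 and 2), Aplf (4 and 3), Fn1 (3 and 2) and Pkm (3 and 2). The KO minus WT difference in promoter share was -3.76 points (-4.49 to -3.05; Fisher's exact test, adjusted p = 4.14e-14), with 5' UTR at -0.785 (4.85e-06), and intergenic DNA at 2.25 (1.55e-06) and 3' UTR at 0.340 (0.00169) the other way. The promoter difference reversed to 6.47 points with equal numbers of best-scoring peaks, to 8.33 by normalised tags and to 5.62 at a fold of at least 6. It kept its sign and grew with at least 3 input tags (-19.7), at an IP density of at least 2 times the mean (-18.7) and 4 times (-6.61), and with promoters within 1 kb of a start (-7.24).

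The 4 lists together covered 60802 separate regions, of which 5756 (9.47%) were in all 4. Regions found only in WT talazoparib, where new peaks that need both the inhibitor and TDG would be counted, numbered 4320 (7.11%). The longer lists had more regions of their own: KO talazoparib 7207, WT DMSO 10856 and KO DMSO 15073. A change in strength at regions that other lists also hold would not be counted here. The counts do not decide whether the inhibitor has an effect that needs TDG. Talazoparib lists of both genotypes shared 484 regions that neither DMSO list held. The WT talazoparib regions were weakly covered: their median IP density was 1.57 times the genome mean, 94.1% had fewer than 3 input tags, 714 had an IP density of at least 2 times the mean and 20 of at least 4 times, and 255 had at least 3 input tags. When all lists were filtered first and regions of WT talazoparib only were then counted anew, there were 852 at an IP density of at least 2 times the mean, 77 at 4 times, 344 with at least 3 input tags, 6211 at a fold of at least 6 and 5826 with equal list lengths. With equal list lengths this was the largest set of 1 list, against 4381 in WT DMSO, 4365 in KO DMSO and 4301 in KO talazoparib. At a fold of at least 6 those sets held 4726, 14372 and 3941.

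**Figure D5:**
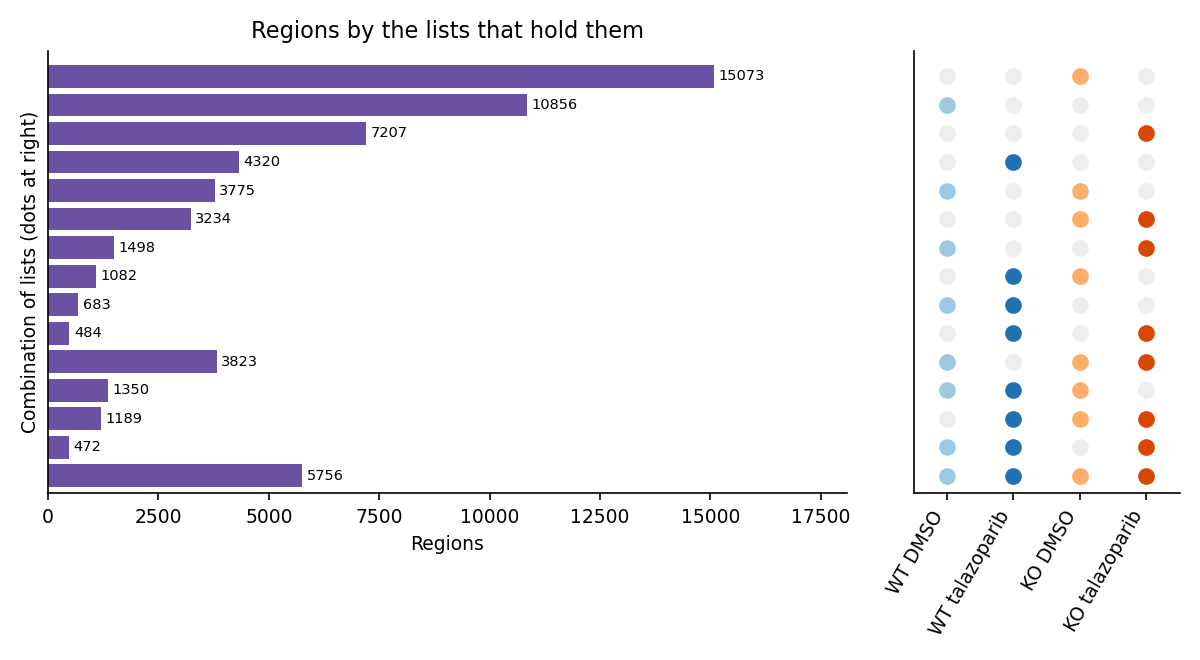
Number of separate regions by the combination of lists that hold them; bar length is the number of regions and coloured dots mark the lists. The longest bars are regions of 1 list only (15073 in KO DMSO, 10856 in WT DMSO, 7207 in KO talazoparib, 4320 in WT talazoparib), and 5756 regions are in all 4 lists.

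Regions of 1 list lay far less often in promoters: 6.23% in WT DMSO, 6.00% in WT talazoparib, 8.41% in KO DMSO and 8.23% in KO talazoparib, still 2.27-fold to 3.12-fold above shifted positions. Introns held 45.6% to 48.1% and intergenic DNA 32.3% to 36.1%. WT talazoparib regions differed from KO talazoparib regions in promoters, by -2.23 points (-3.11 to -1.25; Fisher's exact test, adjusted p = 3.70e-05), and exons, by -1.92 points (adjusted p = 6.01e-05). They also stood apart in repeats, with a median soft-masked share of 29.0% against 23.6% at shifted positions, whereas the other 3 sets were at 12.8% to 16.0%, below shifted positions (two-sided permutation p = 0.002 in each). By gene list, naive pluripotency genes were over-represented in the regions of WT DMSO only (13 of 26, 2.40 times, adjusted permutation p = 0.00525) and KO DMSO only (16, 2.25 times, p = 0.00178). Developmental regulators were so in WT DMSO only (22 of 50, 2.23 times, adjusted permutation p = 9.23e-04), KO DMSO only (27, 2.08 times, p = 9.23e-04) and KO talazoparib only (17, 2.34 times, p = 0.00248), and primed epiblast genes in KO talazoparib only (7 of 16, 2.57 times, p = 0.0480). Random genes for these sets were matched on length and not on CpG density. In the full lists, matching on both moved developmental regulators below expectation. Naive pluripotency and primed epiblast genes then passed in none of the full lists. In the WT talazoparib regions no list passed except chemosensory receptors, with 12 of 1464 genes at 0.127 times expectation; these receptors were also low in the other 3 sets, at 0.0958, 0.0581 and 0.0818 times (adjusted permutation p = 9.23e-04 in each of the 4).

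The highest-scoring regions of WT talazoparib only were an intergenic site on chromosome 13 (115742042 to 115742667, 31.3 normalised tags), an intron of 2900052L18Rik on chromosome 11 (120231099 to 120231599, 13.8 tags), an exon of the deoxyhypusine synthase gene Dhps on chromosome 8 (85071546 to 85072551, 20.6 tags), an intron of the Wnt ligand gene Wnt9a on chromosome 11 (59307685 to 59308311, 11.1 tags) and an exon of Bcan on chromosome 3 (87996981 to 87997481, 8.65 tags). Those of WT DMSO only included the promoters of Necab3 (chromosome 2, 154558617 to 154559117, 13.5 tags) and of the nuclear receptor gene Nr4a2 (chromosome 2, 57114629 to 57115255, 14.6 tags), and intergenic sites 1145 bp from the start of Hic1 and 3472 bp from that of Itgb4. The KO-only regions ranked highest had far more tags, with input far above its mean as well. In KO DMSO only, an intron of Jarid2, a polycomb cofactor gene, had 300.3 normalised tags (chromosome 13, 44869518 to 44870274) with input at 23.1 times its mean, and an intergenic site on chromosome 8 (71432873 to 71433373) had 356.9 with input at 47.2 times. An intron of Camk1d and intergenic sites on chromosomes 3 and Y completed that set. In KO talazoparib only, an intron of the VEGF receptor gene Flt1 (chromosome 5, 147611263 to 147611888) had 442.5 tags with input at 34.2 times, and an intron of Mdga2 (chromosome 12, 67059197 to 67059697) had 171.0 with input at 22.2 times. An intron of the ephrin gene Efna5 and intergenic sites on chromosomes 10 and 12 were the others. Both intergenic sites lay at the end of the assembled sequence. They ended at 130594992 and 120028938, with the last sequenced bases of chromosomes 10 and 12 at 130594993 and 120029022.

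Over the full lists, the best-scoring peaks were partly of the same kind. In WT DMSO they were an intergenic site on chromosome 13 (110743940 to 110744440, input 15.4 times its mean), the promoter of Hjurp, which encodes a centromeric histone chaperone (chromosome 1, 88277254 to 88277754), the shared promoter region of C230088H06Rik and Gm26624 on chromosome 4, a promoter within Zc3h7a on chromosome 16 and an intergenic site on chromosome 19. In WT talazoparib they were intergenic sites on chromosomes 4 and 18, a site past a transcript end on chromosome 3, and promoters within the phosphatase subunit gene Ppp2r5a (chromosome 1, 191396843 to 191397600) and the ubiquitin-conjugating enzyme gene Ube2d3 (chromosome 3, 135438029 to 135439295), the last with 44.7 normalised tags and input at 1.28 times its mean. The chromosome 3 site past a transcript end stopped at 159939574, near the last sequenced base of that chromosome, 159939680. Both KO lists held an intron of the synaptic scaffold gene Gphn (chromosome 12, from 78350765 with DMSO and from 78350761 with talazoparib) and the same site on X, from 170880860 and 170880862. The X site ends at 170881299, the last sequenced base of X in the assembly. The top KO talazoparib peak (chromosome 17, 39846595 to 39847220) lay in CT010467.1, annotated as ribosomal RNA, with 579.9 normalised tags and input at 54.5 times its mean.

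Peaks were spread unevenly over chromosomes. Chromosome 11 was the densest autosome in every list, with 21.8, 12.3, 27.3 and 16.6 peaks per Mb in WT DMSO, WT talazoparib, KO DMSO and KO talazoparib, and chromosome 14 the sparsest, with 7.12, 4.18, 8.73 and 6.42. The X chromosome had 1.80, 1.11, 2.59 and 2.36 peaks per Mb against 11.8, 6.40, 14.6 and 9.83 over the autosomes, which is 0.153, 0.174, 0.177 and 0.240 times as many. Input density at X peaks was lower too, at a median of 0.295, 0.216, 0.282 and 0.384 times the genome mean against 0.417, 0.311, 0.426 and 0.561 on autosomes. These inputs are those at listed peaks, each with a fold of at least 4, and not those of whole chromosomes. The Y chromosome held 2, 1, 2 and 2 peaks.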

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

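The tests of the input totals in KO, of weaker peaks, of list length and of gained peaks in both genotypes, and of autosomes with the gene density of X were chosen only after the result was seen, while the others were set beforehand.

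Fewer peaks were listed with talazoparib than with DMSO, at ratios of 0.544 in WT and 0.676 in KO. In KO a smaller input library does not account for it, since the talazoparib input was 1.14 times the DMSO one, and a smaller IP total does not either: with scores scaled to the talazoparib IP total, DMSO still had 1.643 times the talazoparib peaks in WT and 1.355 times in KO. In WT the input total stays open. Thinning the DMSO input to the talazoparib total left 19052 peaks, 1.227 times the talazoparib list, which lies between the bounds set for either outcome. Thinning could only remove listed peaks, so peaks that a smaller input would add were not counted. The decline was not confined to the weakest peaks: at an IP density of at least 2 times the genome mean the ratios were 0.583 in WT and 0.715 in KO, and at 3 times 0.732 and 0.970. At 4 times the mean they were 0.908 in WT and 1.261 in KO, so a loss of peaks of low and middle density, technical or biological, is a candidate explanation of the shorter lists. It does not produce the larger numbers of strong peaks with talazoparib, with ratios of 1.582 and 2.16 at 6 times the mean, and the cause of these was not tested. An effect of the inhibitor on break numbers was not measured by these lists and stays untested.

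Promoters took a larger share of the talazoparib lists, by 8.48 points in WT and 5.82 in KO. Peaks gained with talazoparib do not account for it, since those found only with talazoparib lay in promoters in 15.939% of cases in WT (14.98 to 17.0) and 11.167% in KO (10.4 to 11.9), below the 25.576% and 24.472% of the DMSO lists, so that adding them lowers the share. Whether talazoparib gave rise to new promoter peaks is not decided by this. In WT the difference of list length may explain it, because lists of equal number gave a difference of -3.626 points. At an IP density of at least 2 times the mean and with at least 3 input tags, where the lists still differed in length, it was 10.068 and 26.155. The 3-tag minimum is the stricter one in the smaller talazoparib input. In KO the part of list length stays open, since lists of equal number gave 2.010 points (1.24 to 2.80) by score and -0.966 (-1.72 to -0.240) by normalized tags. A biological effect on promoters was not excluded in either genotype.

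The X chromosome had few peaks. Male mouse cells carry 1 X, and the strain's cells are not sexed in the labels. When every autosomal peak's tags were scaled from 2 copies down to 1, autosomal peaks per Mb fell so far that X was at 0.848 to 1.421 times their density, so a single copy is consistent with the pattern. Fewer genes on X do not account for it alone. The share of X coding genes with a peak within 5 kb of the start was 0.399 to 0.625 times the autosomal share. The bound set beforehand, below by more than 1.5 times with the interval, was met in 3 lists, while in KO talazoparib the interval reached 0.687. Against the sparsest autosome with at most 1.1 times the gene density of X, X had 0.225 to 0.323 times the peaks per Mb, with no interval above 0.362. No group in the design bears on X, so no biological explanation was tested.

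The effect of talazoparib on where peaks lay differed between genotypes. The ratio of odds ratios, WT over KO, was 1.121 for promoters (1.08 to 1.17), 1.362 for 5' UTRs (1.14 to 1.59), 0.867 for intergenic DNA (0.822 to 0.915) and 0.708 for 3' UTRs (0.556 to 0.891), with adjusted p from block resampling of 0.0047, 0.0047, 0.0047 and 0.0105. For promoters it was 2.68 with at least 3 input tags, a minimum that is not alike between lists of different input totals. It changed side with lists of equal length (0.785), by normalized tags (0.807), at a fold of at least 6 (0.655) and at an IP density of 4 times the mean (0.926). The others turned as well in places: intergenic DNA with lists of equal length (1.161, adjusted p from block resampling 0.0035), by normalized tags (1.057) and at a fold of at least 6 (1.074), 3' UTRs at that fold (1.422), and 5' UTRs at that fold (0.932) and with promoters within 1 kb (0.907) or 5 kb (0.193) of a start. Genotype and flow cells cannot be told apart here either.

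Lists of the 2 treatments overlapped more in KO than in WT, by 11.037 points for DMSO peaks found with talazoparib (10.4 to 11.6) and by 6.655 points for talazoparib peaks found with DMSO (5.75 to 7.53) (95% intervals from resampling blocks). The first changed sign at a fold of at least 6 (12.9% in KO, 16.6% in WT). The other changed sign with at least 3 input tags (63.3% and 77.7%) and with an IP density of at least 2 times the mean (62.9% and 69.0%) or 4 times (61.9% and 62.4%). The KO list of each treatment was longer than the WT one. As a multiple of shifted lists, overlap was higher in WT (27.7-fold and 27.5-fold) than in KO (22.2-fold and 22.5-fold). With equal numbers of best-scoring peaks KO kept the larger shares, 50.1% against 42.5% and 50.7% against 42.6%.

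Peaks on the mitochondrial genome and unplaced contigs, outside all comparisons, held 0.3857% of IP tags in WT DMSO, 0.1324% in WT talazoparib, 1.1141% in KO DMSO and 3.0857% in KO talazoparib. In KO talazoparib 35 peaks on unplaced contigs held 2.71% and 2 on the mitochondrial genome held 0.380%.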

How the results depend on the processing

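No paired analysis was possible because the labels number the IP libraries I to III in each group while the tables hold 1 pooled value per condition. For the same reason the planned tests on read counts per library, with their alternatives (another tool, another scaling, a read minimum, a block for the replicate number) and leaving out each replicate, were not run. Depth limits these lists through the input among other things: 30.01% to 60.7% of peaks had fewer than 3 input tags, and 1 tag more or less then moves the fold. The settings with a minimum of 3 input tags, a minimum IP density, equal list length by normalized tags, or 1 gene per cluster were chosen after seeing the data. Of the main results, 278 values kept their direction, side of the threshold or size, 68 moved, 2 lost their call and 12 reversed. Among single lists, genes and shares, 278 were kept, 115 moved, 86 lost their call, 7 gained one and 7 reversed. All overlaps stayed above shifted or randomly placed lists, by 8.04-fold to 235-fold. Neither kind of list keeps the preference of the peaks for promoters and GC-rich DNA. Peaks of the 4 full lists stayed above shifted positions in GC by 10.1 to 21.7 points and in CpG by 1.27 to 7.39 per 100 bp, and their soft-masked share differed by -19.2 to -11.7 points.

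Fewer peaks pass a stricter setting by construction. At a fold of at least 6, WT DMSO kept 8257 peaks, WT talazoparib 10014, KO DMSO 20258 and KO talazoparib 7422. The regions were 4726 in WT DMSO only, 455 in both WT lists only, 3941 in KO talazoparib only, 1274 in both KO lists only and 364 in all lists. Promoter share, talazoparib minus DMSO in WT, was -2.412 points and KO minus WT with talazoparib 5.624. Lists with an excess of genes numbered 2 in WT DMSO, 2 in WT talazoparib, 4 in KO DMSO and 1 in KO talazoparib, and lists with a deficit 1 in WT DMSO, 1 in WT talazoparib and 1 in KO talazoparib. Repair genes went to 0.7214 in WT talazoparib and developmental regulators to 0.6565 in KO talazoparib.

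With at least 3 input tags, 6119 WT talazoparib and 18968 KO DMSO peaks were left, and regions in WT DMSO only numbered 6870, WT talazoparib only 344, KO DMSO only 5034, KO talazoparib only 4337, both WT lists only 189, both talazoparib lists only 125 and all lists 3824. Promoter share, KO minus WT with DMSO, turned to 4.292, and 1 gene list showed a deficit in WT talazoparib.

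At an IP density of at least 2 times the mean, WT DMSO kept 14257 and WT talazoparib 8316 peaks. Regions in WT DMSO only were 2109, in WT talazoparib only 852, in both WT lists only 217 and in both talazoparib lists only 246, and 1 gene list showed a deficit in WT talazoparib. At 4 times the mean, the peaks were 2578 (WT DMSO), 2340 (WT talazoparib), 5880 (KO DMSO) and 7414 (KO talazoparib). Regions of 1 list only were 110, 77, 1021 and 2581 in that order, those of both WT lists only 14, both KO lists only 1863, both talazoparib lists only 96 and all lists 1339. Promoter share, talazoparib minus DMSO, was -2.016 in WT and -0.520 in KO. Lists with an excess numbered 3, 2, 3 and 4 and with a deficit 1 in each, and developmental regulators were at 0.7368 in KO talazoparib.

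Lists of equal length by score gave 4381 regions in WT DMSO only, 4365 in KO DMSO only, 4301 in KO talazoparib only, 880 in both talazoparib lists only, 1508 in both KO lists only and 3538 in all lists. Promoter share differences were -3.626 (talazoparib minus DMSO in WT), 0.837 (KO minus WT with DMSO) and 6.473 (KO minus WT with talazoparib). By normalized tags they were -5.919, 3.375 and 8.328, and -0.966 for talazoparib minus DMSO in KO. Longer lists reach weaker peaks, which lie less often in promoters, and the cause of the remaining differences was not tested.

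Extending peaks by 1 kb joined regions and left 7178 in WT DMSO only and 4686 in KO talazoparib only. With promoters within 1 kb or 5 kb of a start, KO minus WT with DMSO was -0.388 and -0.247, no longer past the threshold. With the window around the start only, 5 gene lists had an excess in WT DMSO and 1 a deficit in WT talazoparib. Matching on CpG density as well as length left 2, 1, 1 and 2 lists with an excess in WT DMSO, WT talazoparib, KO DMSO and KO talazoparib and 2, 2, 2 and 1 with a deficit, and moved developmental regulators to 0.8033, 0.6996, 0.9217 and 0.8321. The 2-cell-like genes lost their deficit in all 4 lists, developmental regulators gained one in WT DMSO and WT talazoparib, and extraembryonic endoderm genes gained one in KO DMSO (0.6638). That follows from the CpG density of the genes, which is what the matching adds. For the other reversals the cause was not tested.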

Other observations

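Regions held by all 4 lists were rich in promoters and in CpG-rich sequence. Of the WT DMSO, WT talazoparib, KO DMSO and KO talazoparib peaks in such regions, 59.7%, 58.1%, 58.8% and 60.7% lay in promoters and 64.9%, 68.5%, 63.1% and 65.1% were CpG-rich, against 26.7%, 40.4%, 25.4% and 31.0% CpG-rich in the full lists. They were longer than other peaks (median 861 to 1312 bp) and stronger (IP at 3.11 to 5.18 times the genome mean). A peak within 5 kb of the start was present in all 4 lists at 40 of 68 histone genes, 18 of 25 housekeeping genes, 18 of 29 repair genes and 11 of 26 naive pluripotency genes, but at 6 of 50 developmental regulators, 8 of 39 imprinted genes and 1 of 1464 chemosensory receptor genes. Promoter peaks were CpG-rich in 66.2% to 78.5% of cases over the full lists, and peaks elsewhere in 11.9% to 20.6%.

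Few regions of 1 list only were CpG-rich, 4.37%, 5.67%, 7.72% and 6.59% in WT DMSO, WT talazoparib, KO DMSO and KO talazoparib. Those of WT talazoparib stood apart in other measures: 34.3% were mostly soft-masked repeat sequence (10.5% to 18.4% in the other sets of 1 list), and the median region had 1 input tag and a fold of 10.4, the highest of the 4 sets, at a signal of 3.04 normalised tags, the lowest. An intergenic site with high input on X, near 170880860, was held by both KO lists: IP and input stood at 86.8 and 18.7 times their genome means in KO DMSO and at 71.3 and 15.2 times in KO talazoparib, with 0 CpG per 100 bp and 86.3% and 86.7% soft-masked sequence. The site ends at 170881299, the last sequenced base of X in the assembly.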
